A study of Homo sapiens with 24 samples.

How the data were processed

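RNA was measured by bulk RNA sequencing in 24 libraries of MCF7, an estrogen receptor positive human breast cancer cell line. Per the labels, the libraries fall into 12 groups of 2. Each group is 1 of 2 lines, parental MCF7 or a line edited with CRISPR to knock out TP53 (labelled p53KO), at 1 of 6 times: day 0 (untreated) and days 1, 3, 5, 21 and 29 of 50 nM abemaciclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. Nothing in the labels says that the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

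Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 with the genome build GRCh38. The deposited values are raw counts, whole numbers per gene and library, in the column layout that featureCounts writes, per the file headers. The annotation release, the strand setting, the handling of reads that map to several places and whether reads or fragments were counted are not given in the sources used here. Genes that share reads with near-identical copies, overlapping genes and antisense partners are therefore uncertain. Each file held 57500 gene IDs. A symbol came from a table of gene names for 40907 of them and from the GENCODE 29 annotation for another 15991. GENCODE 29 gave a biotype for 56898 IDs and the same chromosome, start and end for 54731.

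Total counts per library ranged from 15667960 to 31219628. Log2 fold changes, CPM values (counts scaled by library size) and p-values were computed from the deposited counts, and the authors' own comparisons were not used here. Genes were filtered with edgeR's filterByExpr over the 12 groups, which left 19085 genes. Libraries were scaled by the trimmed mean of M-values (TMM). The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with robust dispersion estimates. The model had 1 coefficient per group and no covariate, and all 24 libraries entered it, which left 12 residual degrees of freedom. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes within each comparison, with a threshold of 0.05 on the adjusted p. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Fold changes are fitted values, and for a group with 1 to 3 counts in all, counts and CPM are given in their place. CPM values used the TMM-scaled library sizes, and their SD is over the 2 libraries of a group. For groups with 1 to 3 counts and those compared with them, counts and library sizes were summed over the group.

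There were 19 comparisons: each treated day against day 0 within a label, the difference between these responses (p53KO minus parental) at each day, day 29 against day 5 within a label, and p53KO against parental at days 0 and 29. The comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The text names 26 key genes of the cell cycle, the p53 pathway and estrogen response. In each of 6 main comparisons it may name the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold, with an absolute log2 fold change of at least 1, a mean log2 CPM of at least 1 and groups that did not overlap. It may name up to 4 members of each gene list per comparison, those with the smallest adjusted p, and any member named elsewhere.

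The 21 gene lists came from general knowledge and not from these libraries. They were p53 targets, G1/S and DNA replication, G2/M and mitosis, homologous recombination and Fanconi genes, secretory (SASP) factors, type I interferon genes, antigen presentation, estrogen response, luminal epithelial identity, basal and squamous keratinocyte markers, mesenchymal and fibroblast markers, blood and endothelial markers, lysosome and autophagy, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid stress, immediate early genes, nuclear-encoded oxidative phosphorylation, ribosome biogenesis and MYC, matrix, adhesion and YAP targets, and nervous and chromaffin cell genes. Each was tested with fry (edgeR), which asks whether a list's genes moved on balance in 1 direction and does not compare them with other genes. Each was also tested with camera (limma 3.58.1) with a correlation between genes estimated from the data, which does compare them with other genes. Adjusted p-values of lists are over 399 list tests for each method; 261 passed by fry and 70 by camera. Where the text gives 1 adjusted p for a list it is from fry, and a value "with an estimated correlation" is from camera. Members past the threshold are counted over all genes and, where that number differs, adjusted over the list alone. Where only 1 pair of counts is given, both were identical.

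The gene test and both list tests were tested on simulated counts drawn from the means and library sizes of the real libraries. For parental day 5 against day 0, over 17970 simulated genes, 42.9% of genes changed 1.5-fold, 60% of those changed 2-fold and 82.5% of those changed 4-fold were recovered. For the difference of response at day 29, over 17966 genes, these shares were 21.9%, 50.8% and 73%. Between 4.17% and 6.85% of the calls in 4 simulated comparisons were false. All simulated libraries shared the same mean per gene, apart from the genes changed on purpose. The simulated comparison of parental day 5 with day 0 called 144 genes, where the real one called 7344. These shares therefore need not hold for the real comparisons, in which far more genes changed.

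The alternatives were DESeq2's size factors in the same fit, total library size only, no filter on low counts, DESeq2's Wald test (DESeq2 1.42.0), only the groups compared, the replicate number as a block, camera in place of fry, and leaving out each library in turn. Replicates of a group correlated at 0.988 to 0.993, and each entered the tests as a library of its own. Their spread beyond counting noise was less even. The chi-square of counts per degree of freedom ran from 2.103 (parental day 1) to 15.08 (p53KO day 0). The model nevertheless used the same spread per gene for all groups. After TP53 and its targets had been examined, day 0 or day 5 of the other label was added as the reference for 8 comparisons of the late groups. No library was regrouped or left out of the tests.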

Results

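Gene expression was measured by bulk RNA sequencing in MCF7, an estrogen receptor positive human breast cancer line. The series compared parental cells with cells edited by CRISPR to knock out TP53, the gene of the tumour suppressor p53, before and during 50 nM abemaciclib, an inhibitor of the kinases CDK4 and CDK6 that start the cell cycle. There were 12 groups of 2 libraries, 24 in all, at days 0 (untreated), 1, 3, 5, 21 and 29 for each line. Total counts ranged from 15667960 to 31219628 per library. All values rest on n = 2 libraries per group. Mitochondrial genes took 0.635% to 2.7% of the counts in libraries labelled parental. In libraries labelled p53KO they took 1.52% and 1.81% at day 0, 6.11% and 6.08% at day 21, and 4.45% and 6.38% at day 29.

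TP53 (ENSG00000141510, chromosome 17, 7661779 to 7687550 on GRCh38) was examined before any other gene, in every library. In libraries labelled parental, replicates 1 and 2 had 219.9 and 223.4 CPM of TP53 at day 0, 152.4 and 160.3 CPM at day 1, and 146 and 149.4 CPM at day 3. The later values were 117.7 and 116.4 CPM at day 5, 124 and 118.2 CPM at day 21, and 116.4 and 120.9 CPM at day 29. In libraries labelled p53KO the same gene had 290 and 281.1 CPM at day 0, 184.7 and 194.9 CPM at day 1, and 136.3 and 157.5 CPM at day 3. At day 5 it had 138.8 and 139.3 CPM, at day 21 it had 69.78 and 71.08 CPM, and at day 29 it had 81.35 and 65 CPM. TP53 was higher in libraries labelled p53KO at day 0 (log2 difference 0.37 ± 0.08 SE, adjusted p = 0.000454), day 1 (0.28 ± 0.08, adjusted p = 0.00726) and day 5 (0.25 ± 0.08, adjusted p = 0.0149), and did not pass at day 3 (-0.01 ± 0.08, adjusted p = 0.945). It was lower in them at day 21 (-0.78 ± 0.08, adjusted p = 1.65e-09) and day 29 (-0.69 ± 0.09, adjusted p = 4.55e-08). The edited position is not given in the sources used here, and an edited gene can still be transcribed, so the level of TP53 alone does not test the edit.

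The p53 targets, genes that p53 switches on, went against the labels at days 0 to 5 and along with them at days 21 and 29. At day 0, 21 of 42 were higher and 5 lower in libraries labelled p53KO (25 and 5 adjusted over the list alone), with a median log2 difference of 0.30 and an adjusted p of 3.3e-07, or adjusted p = 0.0547 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, differed by 0.40 ± 0.09 (adjusted p = 0.000643) and PHLDA3 by 1.87 ± 0.12 (adjusted p = 2.95e-15). EDA2R, a receptor gene, differed by 3.70 ± 0.33 (adjusted p = 3.16e-11). KITLG, a growth factor gene on the same list, went the other way (-1.91 ± 0.10, adjusted p = 2.8e-17). At day 29, 6 of the 42 targets were higher and 20 lower in libraries labelled p53KO (6 and 21 adjusted over the list alone), with a median of -0.26 and an adjusted p of 2.57e-06, or adjusted p = 0.114 with an estimated correlation. PHLDA3 then differed by -1.71 ± 0.12, KITLG by 1.60 ± 0.10 and MDM2, which codes for the ligase that degrades p53, by -0.60 ± 0.08, while CDKN1A was higher in them (0.55 ± 0.09, adjusted p = 1.26e-05). The days between were compared only after TP53 had been examined. CDKN1A was higher at day 1 (0.33 ± 0.09, adjusted p = 0.00469), did not pass at day 3 (0.09 ± 0.09, adjusted p = 0.449) or day 5 (0.20 ± 0.09, adjusted p = 0.0819), and was lower at day 21 (-0.995 ± 0.096, adjusted p = 1.19e-10). Of the targets as a list, the higher and lower targets numbered 24 and 4 at day 1, 21 and 6 at day 3, 19 and 6 at day 5, and 6 and 24 at day 21. By fry the list had an unadjusted p under 0.05 at each of these days (4.34e-09, 1.91e-08, 5.68e-06 and 5.79e-08). With an estimated correlation the unadjusted p was 0.00154, 0.00417, 0.0683 and 0.0345, so day 5 was not under 0.05. These values were not adjusted over the list tests, unlike those above for days 0 and 29. The unadjusted p with an estimated correlation was 0.00986 at day 0 and 0.0254 at day 29, and neither passed once adjusted. Since the knockout could not be read from the libraries that carry its name at days 0 to 5, every group is named by its label, and each direction between lines is a direction between labels.

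**Figure D1:**
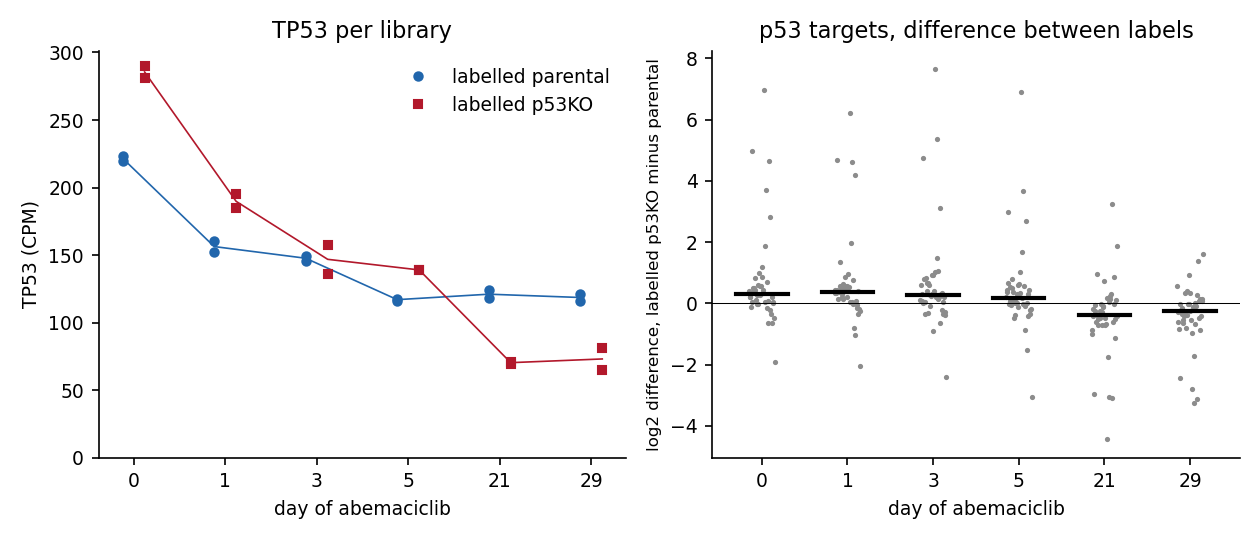
TP53 in each library (left, CPM, with lines through the mean of 2 libraries) and the 42 p53 targets as log2 differences between libraries labelled p53KO and parental at the same day (right, points are genes, bars are medians). The median was 0.30 at day 0 and -0.26 at day 29.

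The difference between the labels as a whole turned over between days 5 and 21. At day 0, 1990 genes differed at least 2-fold. Of these, 68.6% differed past the threshold in the same direction at day 5, and 1.36% in the opposite direction. At day 21 the shares were 5.03% and 58%, and at day 29 they were 3.57% and 55.2%. The 1099 genes that were opposite at day 29 compare with 361 if the days were independent. Genes higher in libraries labelled p53KO at day 0 had a median of -0.88 at day 29, and genes lower had a median of 0.86. Across all 19085 genes tested the correlation with day 0 was 0.544 at day 5 and -0.476 at day 29, though genes are not independent replicates. PRIM1 (ENSG00000198056, chromosome 12), a subunit of the DNA primase, had 459 ± 53.5 CPM (SD) in libraries labelled parental and 107 ± 0.104 CPM in those labelled p53KO at day 0, and 20.4 ± 4.11 and 1000 ± 38.9 CPM at day 29. BASP1 went from 0.518 ± 0.285 against 63.6 ± 9.88 CPM to 54.4 ± 9.2 against 3.39 ± 0.306 CPM.

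**Figure D2:**
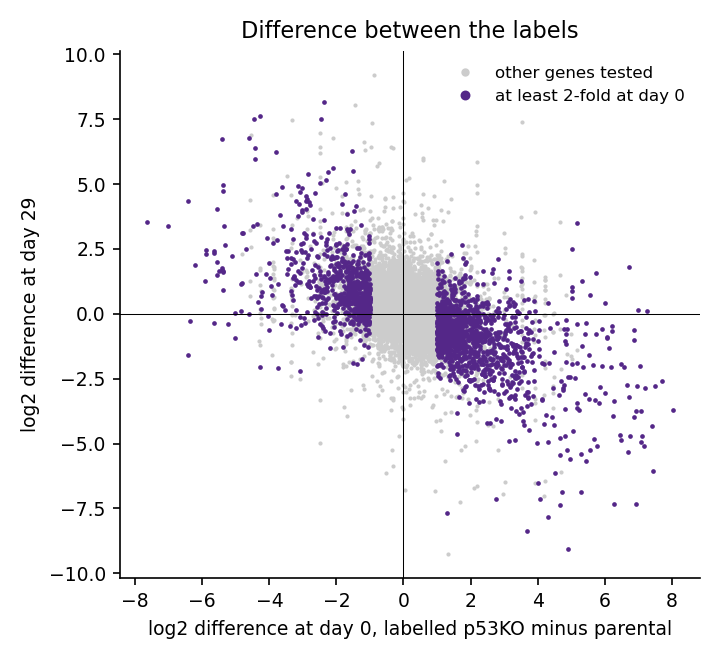
Log2 difference between libraries labelled p53KO and parental at day 0 (x axis) and day 29 (y axis), 1 point per gene tested. The 1990 genes that differed at least 2-fold at day 0 are in purple, and 55.2% of them differed past the threshold in the opposite direction at day 29.

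Untreated cells of both labels were compared at day 0. Among the well-counted protein-coding genes of the naming rule, those furthest above parental in libraries labelled p53KO were BASP1 (6.87 ± 0.26, adjusted p = 1.05e-17), RAMP3, part of a peptide hormone receptor (6.26 ± 0.23), SEMA5A, an axon guidance gene (5.69 ± 0.29), and IGSF1 (4.78 ± 0.14). Those furthest below were SNCG, gamma-synuclein (-5.38 ± 0.23, adjusted p = 7.52e-20), CHRNA9, a nicotinic receptor subunit (-5.36 ± 0.20), ADGRF5 (-4.42 ± 0.25) and TM4SF1 (-4.41 ± 0.19). Luminal epithelial genes were higher in libraries labelled p53KO, 14 of 22 against 5 lower (14 and 6 adjusted over the list alone; median 0.40, adjusted p = 3.37e-07), led by AGR2 (4.56 ± 0.10) and MLPH (1.33 ± 0.08). Antigen presentation genes were higher, 7 of 21 against 1 lower (median 0.28, adjusted p = 7.38e-06, adjusted p = 0.145 with an estimated correlation). Among them HLA-C (2.26 ± 0.11) and HLA-B (2.13 ± 0.17) are uncertain, since they share reads with near-identical copies. Unfolded protein and amino acid stress genes were lower, 14 of 27 against 5 higher (5 and 15 adjusted over the list alone; median -0.27, adjusted p = 6.49e-06, adjusted p = 0.163 with an estimated correlation). MYC was lower (-0.64 ± 0.08). MDM2 did not pass (0.20 ± 0.08, adjusted p = 0.0557), but did without parental day 0 replicate 2 (0.0213) or p53KO day 0 replicate 1 (0.0195). CDKN2A, the gene of the cell cycle inhibitor p16, was lower (-1.01 ± 0.28, adjusted p = 0.00379; 0.178 without p53KO day 0 replicate 1), as was CCND1, cyclin D1 (-0.36 ± 0.09, adjusted p = 0.00156; 0.0537 without parental day 0 replicate 2). The p53 target SPATA18 had 1 count (0.0235 CPM) in the libraries labelled parental and 198 (3.56 CPM) in those labelled p53KO. In all, 3755 genes were higher and 3661 lower, 1266 and 724 of them at least 2-fold.

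The course of treatment in libraries labelled parental over days 1 to 5 showed the loss of cell cycle expression. By day 1, 37 of 39 G1/S and DNA replication genes had fallen and none had risen (median -2.48, adjusted p = 8.91e-11). CDC45 (ENSG00000093009, chromosome 22), a helicase cofactor, fell by 4.68 ± 0.15 on the log2 scale (adjusted p = 8.98e-23) and MCM7, a helicase subunit, by 2.53 ± 0.09. E2F1, the transcription factor released by CDK4 and CDK6, fell by 2.94 ± 0.16 and CCNE2, cyclin E2, by 3.10 ± 0.16. All 36 G2/M and mitosis genes were lower at each of days 1, 3 and 5, with medians of -1.95, -4.03 and -2.42 (adjusted p = 6.92e-09, 5.03e-11 and 8.98e-10). MKI67, the proliferation marker Ki-67, stood at 479 ± 93.6 CPM (SD) at day 0, 87.5 ± 1.15 at day 1, 11.6 ± 0.4 at day 3 and 83.4 ± 0.382 at day 5. Homologous recombination genes such as BRCA1 (-2.57 ± 0.12 at day 1) fell with them, 22 of 23 at day 1 (median -2.32, adjusted p = 5.35e-11). Type I interferon genes were higher at day 1, 18 of 41 with none lower (20 and none adjusted over the list alone; median 0.62, adjusted p = 0.00319, adjusted p = 0.313 with an estimated correlation), among them RIGI (0.98 ± 0.15) and OAS1 (1.37 ± 0.25). The count past the threshold was 1450 higher and 1849 lower at day 1, 3732 and 3762 at day 3, and 3473 and 3871 at day 5. With total library size only, the share of higher genes at day 3 moved from 49.8% to 39.9%. The 3299 genes of day 1 became 2122 without replicate 1 of day 1 and 1985 without replicate 2.

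Gene groups outside the cell cycle had changed by day 5 as well. In libraries labelled parental, 22 of 25 cholesterol synthesis genes were lower and none higher (median -1.53, adjusted p = 2.12e-11). STARD4 (ENSG00000164211, chromosome 5), a sterol carrier, fell by 4.38 ± 0.18 (adjusted p = 3.53e-20), INSIG1 by 2.73 ± 0.08, HMGCS1 by 2.20 ± 0.08 and LDLR, the lipoprotein receptor, by 2.06 ± 0.08. SCD, which desaturates fatty acids, fell by 3.27 ± 0.09. Matrix, adhesion and YAP target genes were higher, 15 of 23 with none lower (median 0.73, adjusted p = 2.77e-07), including the integrin ITGB6 (1.94 ± 0.12) and ANXA3 (2.31 ± 0.14). Secretory factors were higher, 10 of 21 with none lower (median 0.37, adjusted p = 2.81e-08), led by IGFBP5, an insulin-like growth factor binding protein (2.93 ± 0.10, adjusted p = 4.66e-22). Estrogen response genes were higher, 16 of 32 against 3 lower (median 0.36, adjusted p = 3.51e-05, adjusted p = 0.244 with an estimated correlation), among them PGR, the progesterone receptor (1.31 ± 0.14), and CCND1, cyclin D1 (0.85 ± 0.09). Oxidative phosphorylation genes were lower, 22 of 30 with none higher (25 and none adjusted over the list alone; median -0.48, adjusted p = 0.000209, adjusted p = 0.381 with an estimated correlation). The p53 targets went both ways, 11 higher and 14 lower, with TP53INP1 up by 1.75 ± 0.10 and DDB2 down (-1.39 ± 0.09). On that list the median was -0.03, the mean 0.08 and the adjusted p 0.888, and TP53 itself fell by 0.92 ± 0.08. Among well-counted protein-coding genes, others that rose strongly were NOS3, endothelial nitric oxide synthase (3.73 ± 0.25), the zinc transporter SLC30A8 (3.65 ± 0.24) and the collagen gene COL5A1 (3.52 ± 0.16).

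**Figure D3:**
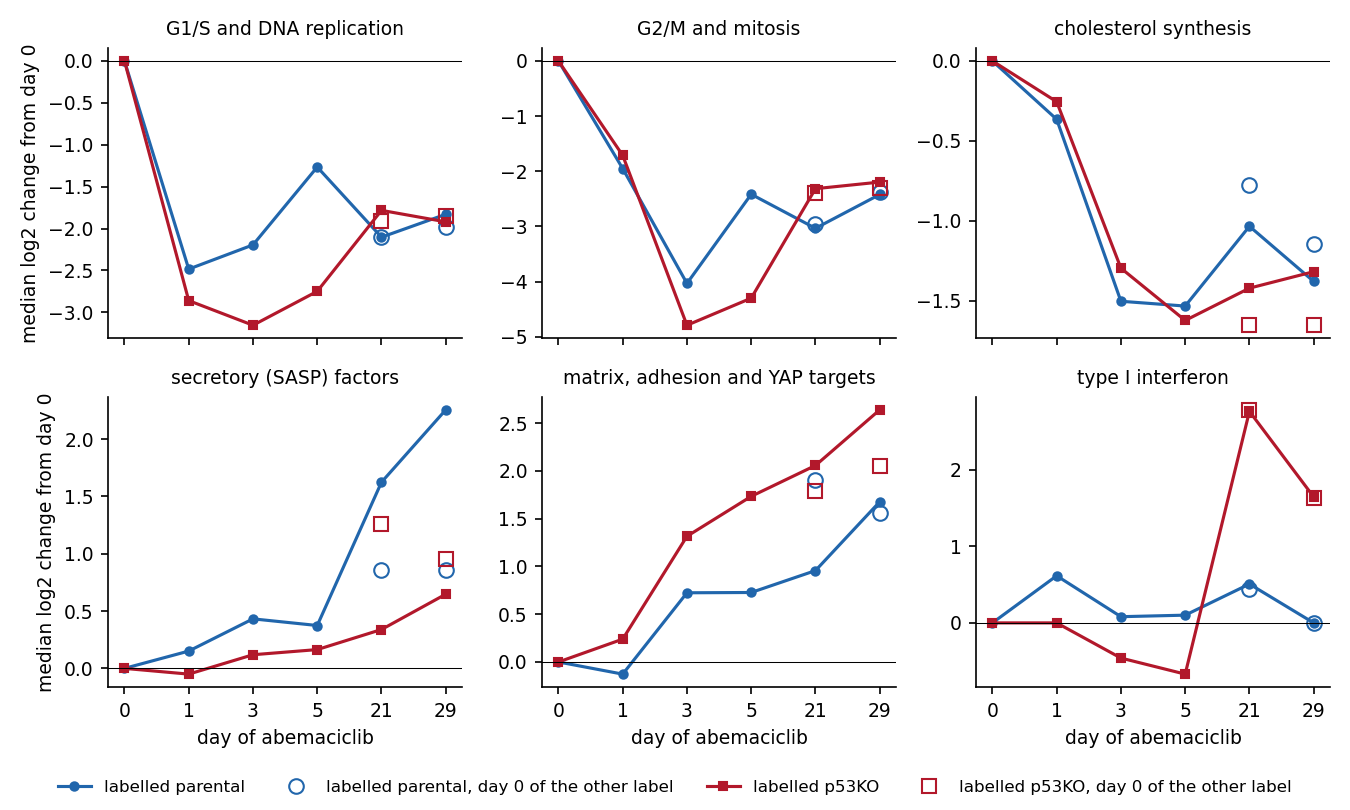
Median log2 change from day 0 of 6 gene lists (y axis) over the days of abemaciclib (x axis), in libraries labelled parental (blue circles) and p53KO (red squares). Open symbols at days 21 and 29 take day 0 of the other label as the reference. The G2/M median in libraries labelled parental was -4.03 at day 3 and -2.42 at day 5.

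Cell cycle genes also fell in libraries labelled p53KO over days 1 to 5. At day 1, 38 of 39 G1/S genes were lower (39 adjusted over the list alone), none was higher, the median was -2.86 and the adjusted p was 5.03e-11. CDC45 fell by 4.79 ± 0.15 and E2F1 by 3.72 ± 0.17. At day 5 the G1/S median was -2.75, with 38 lower and 1 higher, and all 36 G2/M genes were lower with a median of -4.30 (adjusted p = 3.63e-11). KIF20A, a mitotic kinesin, fell by 6.09 ± 0.17 (adjusted p = 1.55e-24), AURKB, the Aurora B kinase, by 6.02 ± 0.22 and PIMREG, a mitotic regulator, by 6.49 ± 0.27. MKI67 stood at 325 ± 39.7 CPM (SD) at day 0, 6 ± 0.191 at day 3 and 8.47 ± 2.14 at day 5. Cholesterol synthesis genes were lower at day 5, 23 of 25 with none higher (median -1.62, adjusted p = 3.2e-11), including ACAT2 (-2.96 ± 0.13) and LDLR (-2.58 ± 0.08). Matrix, adhesion and YAP target genes were higher, 15 of 23 against 1 lower (median 1.73, adjusted p = 5.82e-09), including ITGB6 (3.48 ± 0.14) and CD44 (1.73 ± 0.08). Secretory factors were higher, 8 of 21 against 3 lower (median 0.16, adjusted p = 3.86e-08, adjusted p = 0.0576 with an estimated correlation), with IGFBP5 up by 4.09 ± 0.11. Interferon genes were lower, 17 of 41 against 3 higher (median -0.67, adjusted p = 0.00598, adjusted p = 0.742 with an estimated correlation), with OAS3, an antiviral enzyme, at -2.20 ± 0.16. GABRP (ENSG00000094755, chromosome 5), a GABA receptor subunit, rose most among the well-counted protein-coding genes (7.33 ± 0.34, adjusted p = 2.72e-19), from 0.149 ± 0.115 to 23.9 ± 1.5 CPM, followed by the kinase gene HCK (4.96 ± 0.17).

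In these libraries 2434 genes were higher and 2971 lower at day 1, 4099 and 4558 at day 3, and 4833 and 5097 at day 5. The 5405 genes of day 1 became 2966 without replicate 1 of day 0 and 3142 without replicate 1 of day 1. The share of them that was higher, 45%, became 60.3% with total library size only, a scaling that moved the median of all genes to 0.122.

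Whether the response differed between labels was tested directly as the difference of the changes from day 0. At day 5 the fall of cell cycle genes was larger in libraries labelled p53KO. Of 39 G1/S genes, 37 differed downward and none upward (median -1.40, adjusted p = 1.97e-07), and of 36 G2/M genes all 36 did (median -1.84, adjusted p = 1.72e-06). MKI67 differed by -2.76 ± 0.31 (adjusted p = 2.38e-05), CDC45 by -2.54 ± 0.19, KIF20A by -2.55 ± 0.22 and CCNE2 by -2.24 ± 0.22. Homologous recombination genes differed likewise, 18 of 23 lower with none higher (19 and none adjusted over the list alone; median -1.19, adjusted p = 5.59e-07). At day 3 the G1/S genes already differed, 27 lower with none higher (30 and none adjusted over the list alone; median -0.77, adjusted p = 4.13e-05). Interferon genes differed at day 5, 14 of 41 lower with none higher (17 and none adjusted over the list alone; median -0.76, adjusted p = 0.0037, adjusted p = 0.286 with an estimated correlation), with BST2, an antiviral membrane protein, at -1.58 ± 0.18. The rise of IGFBP5 was larger in libraries labelled p53KO (1.16 ± 0.14, adjusted p = 1.25e-07). At day 1 PRIM1 had the clearest difference (-2.14 ± 0.17, adjusted p = 1.27e-08), from 459 ± 53.5 to 456 ± 1.58 CPM in libraries labelled parental and from 107 ± 0.104 to 24 ± 0.457 CPM in those labelled p53KO.

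The genes past the threshold for this difference numbered 32 at day 1 (12 higher, 20 lower), 2932 at day 3 (963 higher, 1969 lower) and 3198 at day 5 (1117 higher, 2081 lower), with 2069 at an unadjusted p under 0.05 at day 1. The count at day 1 rested on single libraries. Leaving out parental day 0 replicate 1 or 2 gave 133 or 4, parental day 1 replicate 1 or 2 gave 6 or 7, p53KO day 0 replicate 1 or 2 gave 3 or 510, and p53KO day 1 replicate 1 or 2 gave 57 or 11. At day 3 the count became 1863 without parental day 0 replicate 2, 1610 without parental day 3 replicate 2, 1729 without p53KO day 0 replicate 1 and 1831 without p53KO day 3 replicate 1, and at day 5 it became 1964 without p53KO day 5 replicate 1. With total library size only, the share of higher genes moved from 32.8% to 57.8% at day 3 and from 34.9% to 47.6% at day 5.

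Libraries labelled parental at days 21 and 29 kept low cell cycle expression and gained secretory, adhesion and basal genes. Because the difference between labels turned over, each late comparison was also made against day 0 of the other label, a reference chosen after the data were seen. At day 29, 38 of 39 G1/S genes were lower with none higher (median -1.83, adjusted p = 3.79e-10; median -1.99 with the other reference), and all 36 G2/M genes were lower (median -2.42, adjusted p = 8.54e-10; -2.38 with the other reference). MKI67 was at 27 ± 3.26 CPM (SD) at day 21 and 55 ± 14 CPM at day 29. Secretory factors were higher, 16 of 21 against 2 lower (median 2.26, adjusted p = 2.12e-11; 0.86 with the other reference), with IGFBP5 at 900 ± 85.2 CPM after 33.1 ± 4.78 CPM at day 0. INHBA, an activin subunit, had 2 counts (0.047 CPM) at day 0 and 834 (17.7 CPM) at day 29. Matrix, adhesion and YAP target genes were higher, 14 of 23 against 3 lower (median 1.68, adjusted p = 1.38e-10; 1.56 with the other reference), with the caveolin gene CAV1 (ENSG00000105974, chromosome 7) going from 0.275 to 67.4 CPM (log2 5.87 with the other reference) and ANXA1 up by 7.28 ± 0.32 (6.19). Basal keratinocyte markers were higher, 10 of 14 against 1 lower (median 2.17, adjusted p = 6.38e-11; 1.52 with the other reference), among them TP63, a basal cell regulator (4.42 ± 0.53, or 3.40). CDK6, a target of the drug, rose by 4.89 ± 0.32 (adjusted p = 2.99e-15), or 3.77 with the other reference, from 0.492 ± 0.322 to 15.4 ± 1.52 CPM.

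Cholesterol synthesis genes remained low at day 29 in libraries labelled parental, 21 of 25 against 2 higher (median -1.38, adjusted p = 5.03e-11; -1.14 with the other reference), with LDLR at -1.94 ± 0.08. The estrogen-responsive genes GREB1 (1.56 ± 0.08) and PGR (1.54 ± 0.14) were higher. Genes that fell strongly included CHRNA9 (-6.34 ± 0.23, or -0.98 with the other reference), INSYN1 (-5.51 ± 0.25, or -3.25) and SNCG (-5.27 ± 0.23), which reached 0.11 with the other reference. The direction of the p53 targets depended on the reference. They were 17 higher and 14 lower (17 and 15 adjusted over the list alone; median 0.02, adjusted p = 0.017, adjusted p = 0.753 with an estimated correlation), and passed downward with a median of -0.34 with the other reference. Their mean in the planned test was 0.48. Luminal genes were 11 higher and 8 lower of 22 (12 and 8 adjusted over the list alone; median 0.19, adjusted p = 3.62e-06, adjusted p = 0.314 with an estimated correlation), and their test passed downward with the other reference, although the median there was 0.01. At day 21, 5666 genes were higher and 5794 lower, and at day 29, 5542 were higher and 5825 lower.

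**Figure D4:**
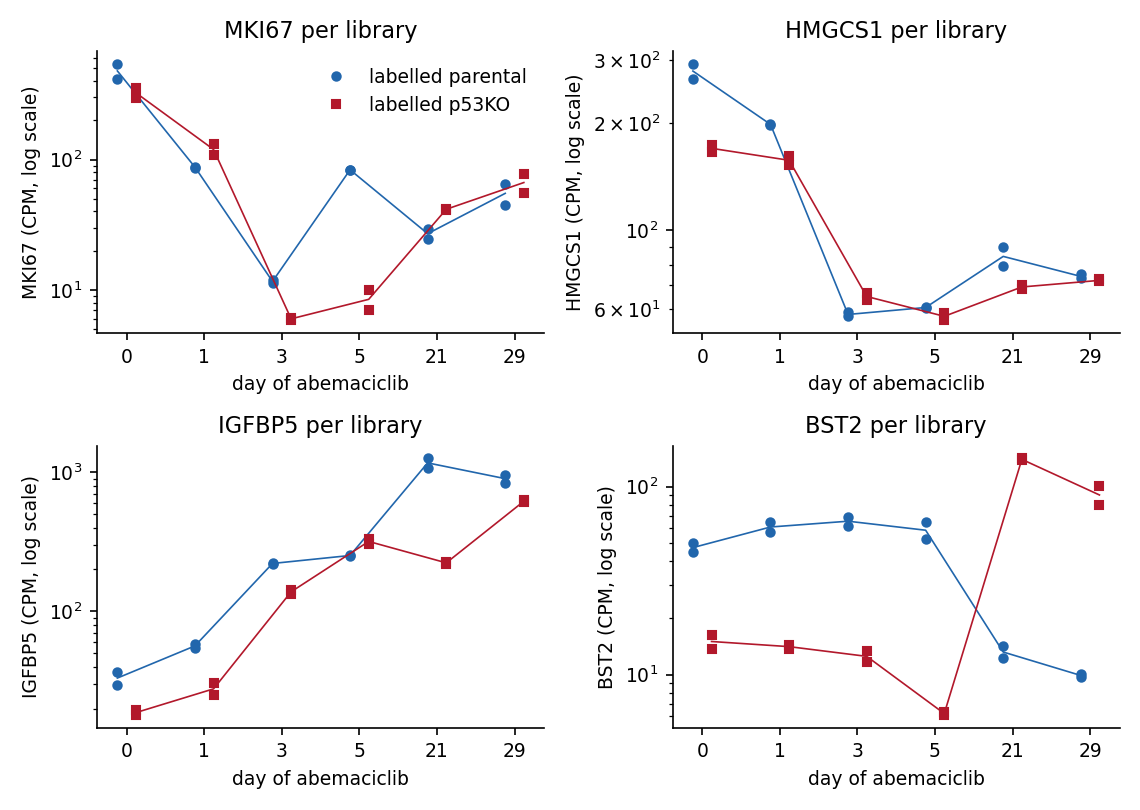
CPM on a log scale (y axis) of MKI67, HMGCS1, IGFBP5 and BST2 in each library (points) over the days of abemaciclib (x axis), with lines through group means, in libraries labelled parental (blue circles) and p53KO (red squares). BST2 was at 15 ± 1.8 CPM (SD) at day 0 and 140 ± 2.21 CPM at day 21 in libraries labelled p53KO.

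Libraries labelled p53KO at day 21 stood out by interferon genes. Of 41, 39 were higher than at day 0 and none was lower (median 2.77, adjusted p = 2.52e-09; 2.79 with the other reference). DDX60 (ENSG00000137628, chromosome 4), an antiviral helicase, rose by 4.98 ± 0.21 (adjusted p = 6.95e-19; 4.21 with the other reference), the RNA sensor gene RIGI by 3.17 ± 0.14 (3.04) and BST2 by 3.22 ± 0.12 (1.56). Mitochondrial genes took 6.11% and 6.08% of the counts in these libraries. Antigen presentation genes were higher, 15 of 21 against 2 lower (median 1.42, adjusted p = 1.29e-08, adjusted p = 0.0652 with an estimated correlation; median 2.24 with the other reference). At day 29, 30 interferon genes were higher and 3 lower (median 1.65, adjusted p = 2.72e-06, adjusted p = 0.206 with an estimated correlation; 1.63 with the other reference).

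At day 29 in libraries labelled p53KO, 37 of 39 G1/S genes were lower and 2 higher (median -1.92, adjusted p = 3.66e-10; -1.85 with the other reference), and all 36 G2/M genes were lower (median -2.20, adjusted p = 8.22e-10; -2.30 with the other reference). MKI67 was at 66.6 ± 16.3 CPM (SD). Matrix, adhesion and YAP target genes were higher, 18 of 23 against 2 lower (median 2.64, adjusted p = 1.62e-10; 2.05 with the other reference), with ITGB6 at 4.52 ± 0.14 (2.28 with the other reference) and the YAP target ANKRD1 at 5.42 ± 0.29 (4.22). Secretory factors were higher, 11 of 21 against 2 lower (median 0.65, adjusted p = 2.94e-10; 0.96 with the other reference), with IGFBP5 at 5.05 ± 0.11 (4.23). Cholesterol synthesis genes were lower, 24 of 25 against 1 higher (median -1.32, adjusted p = 3.63e-11; -1.65 with the other reference). Genes that rose strongly included GPNMB, a lysosome-related glycoprotein (6.21 ± 0.32, or 4.44), SLC30A8 (6.12 ± 0.27, or 4.62) and NOS3 (5.41 ± 0.18, or 6.36). CDK6 rose by 2.71 ± 0.28, or 3.83 with the other reference. TP53 fell by 1.96 ± 0.09 and the p53 targets with it, 26 lower and 8 higher (26 and 9 adjusted over the list alone; median -0.51, adjusted p = 2.63e-09; -0.18 with the other reference). Of the genes that fell strongly, SEMA5A (-4.74 ± 0.26), BASP1 (-4.22 ± 0.19) and CRISPLD1 (-3.35 ± 0.16) became 0.95, 2.65 and 0.67 with the other reference. Of these, SEMA5A did not pass there (adjusted p = 0.123). At day 21, 5973 genes were higher and 6466 lower, and at day 29, 5576 were higher and 5894 lower.

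The late difference of response, p53KO minus parental, carried the turn of the label difference and is reported as labelled. At day 29 the values reached 10.80 ± 0.44 for ADGRF5 and 10.13 ± 0.33 for SNCG, and -10.86 ± 0.32 for BASP1, -10.51 ± 0.38 for SEMA5A and -10.21 ± 0.26 for RAMP3. With the other label's day 0 as the reference these became 1.97, -0.63, 2.88, 0.87 and 2.31. AGR2 turned from -4.90 ± 0.14 to 4.23. The p53 targets differed downward, 22 lower and 5 higher (23 and 7 adjusted over the list alone; median -0.53, adjusted p = 2.25e-08), and did not pass with the other reference (median 0.09). Luminal genes differed downward, 15 of 22 against 3 upward (median -0.78, adjusted p = 3.82e-08), and passed upward with the other reference (median 0.01). Interferon genes differed upward under both references at day 21, 31 of 41 against 3 lower (median 2.53, adjusted p = 9.95e-07, adjusted p = 0.101 with an estimated correlation; 2.46 with the other reference). PRIM1 also differed upward under both at day 29 (7.73 ± 0.18, or 3.52), as did BST2 (4.84 ± 0.17, or 1.53). The genes past the threshold were 4157 higher and 4996 lower at day 21 and 4249 higher and 4465 lower at day 29. These totals, 9153 and 8714, became 6053 and 3997 with the other reference.

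Late and early treatment were compared within each label as day 29 against day 5, and against day 5 of the other label after the data were seen. In libraries labelled parental, secretory factors were higher at day 29, 14 of 21 against 4 lower (median 1.40, adjusted p = 8.91e-11; 1.20 with the other reference). Basal markers were higher, 8 of 14 with none lower (9 and none adjusted over the list alone; median 1.29, adjusted p = 9.94e-11; 1.19 with the other reference). CAV1 rose by 8.25 ± 0.23 (3.68 with the other reference), CDK6 by 3.96 ± 0.28 (2.31) and LAMC2 by 3.57 ± 0.29 (1.39), while CD44 moved from 2.99 ± 0.09 to -0.17. In libraries labelled p53KO, all 36 G2/M genes were higher at day 29 (median 2.22, adjusted p = 7.8e-08), but not past the threshold against the other reference (median 0.23), where MKI67 moved from 3.00 ± 0.24 to -0.32 and CDK1 from 2.42 ± 0.13 to 0.11. In libraries labelled parental the G2/M list did not pass (9 higher and 9 lower, median -0.06, mean 0.08, adjusted p = 0.676) but was higher with the other reference (median 1.84). In those labelled p53KO, interferon genes were higher, 35 of 41 with none lower (36 and none adjusted over the list alone; median 2.44, adjusted p = 2.75e-07; 1.38 with the other reference), with DDX60 at 3.93 ± 0.24 (2.10). The p53 targets were lower, 23 against 4 higher (24 and 4 adjusted over the list alone; median -0.33, adjusted p = 6.76e-08; -0.16 with the other reference). In all, 4816 genes were higher and 5009 lower in libraries labelled parental, and 3409 and 3644 in those labelled p53KO. The total of 9825 for libraries labelled parental became 3778 with the other reference.

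At day 29 the labels were compared with each other. Interferon genes were higher in libraries labelled p53KO, 29 of 41 against 4 lower (30 and 4 adjusted over the list alone; median 1.61, adjusted p = 6.36e-06, adjusted p = 0.0652 with an estimated correlation), with BST2 at 3.19 ± 0.12 and DDX60 at 3.28 ± 0.22, beside mitochondrial shares of 4.45% and 6.38%. Secretory factors were lower in them, 12 of 21 against 4 higher (median -0.41, adjusted p = 8.41e-08), and INHBA had 1 count (0.024 CPM) against 834 (17.7 CPM). Basal markers were lower, 7 of 14 against 2 higher (7 and 3 adjusted over the list alone; median -0.22, adjusted p = 2.07e-07), with ITGB4 at -1.91 ± 0.07. The adhesion genes CD44 (-2.30 ± 0.08) and CAV1 (-2.75 ± 0.14) were lower and PRIM1 was higher (5.63 ± 0.14, adjusted p = 8.06e-22). Cell cycle lists did not pass here, with medians of 0.06 for G1/S genes (adjusted p = 0.137) and 0.23 for G2/M genes (adjusted p = 0.337). G1/S genes did pass without parental day 29 replicate 2 (0.0406) or p53KO day 29 replicate 2 (0.00425), and G2/M genes without the latter (0.0271). In all, 3187 genes were higher and 3619 lower, 1047 and 971 of them at least 2-fold.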

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

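The results given first are differences between the responses of the 2 labels that were tested directly. The 3 patterns weighed after them also draw on changes within a label and on the labels compared at each day. Of the tests of explanations, that of library scaling was written before its result was seen, and the others were chosen after.

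Cell cycle genes fell further in libraries labelled p53KO at days 3 and 5, and less far at day 21. The G1/S list differed at day 3 (median log2 -0.77) and day 5 (-1.40), and so did G2/M genes (-1.84) and homologous recombination genes (-1.19) at day 5. G2/M genes passed downward by fry at day 3 too, but not with total library size only (adjusted p = 0.0693). Single genes at day 5 were MKI67 (-2.76), E2F1 (-1.86), CCNE2 (-2.24), CDC45 (-2.54), CDK1 (-2.20) and KIF20A (-2.55). At day 21 the difference was upward for G1/S genes (median 0.19, adjusted p = 0.0173), G2/M genes (0.60, adjusted p = 0.00121) and homologous recombination genes (0.83, adjusted p = 0.000258), but none of these passed with an estimated correlation (adjusted p = 0.688, 0.473 and 0.43). With day 0 of the other label as the reference, chosen after the data were seen, the medians were 0.37, 0.51 and 0.34. G1/S genes did not pass without parental day 21 replicate 2 (0.0648) or p53KO day 0 replicate 2 (0.0927). The interferon list differed by -0.76 at day 5, with BST2 at -1.58, but the list did not pass with an estimated correlation (adjusted p = 0.286). IGFBP5 differed upward by 1.16 at day 5.

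At day 1 the difference covered PRIM1 (-2.14), a DNA replication gene, and CDT1 (-0.66), OAS3 (-1.04) and IRF7 (-1.23). PRIM1 passed without any 1 library. The other genes did not pass without parental day 0 replicate 2 (adjusted p = 0.198, 0.158 and 0.249), parental day 1 replicate 1 (0.0792, 0.0737 and 0.0697), parental day 1 replicate 2 (0.212, 0.182 and 0.236), p53KO day 0 replicate 1 (0.347, 0.198 and 0.35) or p53KO day 1 replicate 2 (0.134, 0.0664 and 0.103). Without p53KO day 1 replicate 1, OAS3 (0.0633) and IRF7 (0.0873) did not pass.

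At day 29 the response differed upward in libraries labelled p53KO for ADGRF5 (10.80), SNCG (10.13), CHRNA9 (8.76), THRSP (8.44), PRIM1 (7.73), INSYN1 (7.71), GATA4 (7.04), CLEC3A (7.03) and BST2 (4.84). With day 0 of the other label as the reference, a choice made after the data were seen, these became 1.97, -0.63, -1.96, 0.81, 3.52, 3.20, 0.98, 3.99 and 1.53, of which SNCG and GATA4 did not pass. As labelled, it differed downward for BASP1 (-10.86), SEMA5A (-10.51), RAMP3 (-10.21), SMARCA1 (-7.90), EPHA4 (-7.67), IGSF1 (-7.53), HTRA1 (-7.45), SERPINA1 (-7.25) and AGR2 (-4.90). With the other reference these became 2.88, 0.87, 2.31, -0.69, -0.57, 2.03, 0.80, 0.12 and 4.23, of which BASP1, RAMP3, IGSF1 and AGR2 passed, all upward. TP53 (-1.06), MDM2 (-0.80), PHLDA3 (-3.58) and EDA2R (-6.96) differed downward as labelled, and with the other reference became -0.33, -0.40, 0.16 and 0.44, of which TP53 and MDM2 passed.

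Among lists, the p53 target list differed by -0.57 at day 21 and -0.53 at day 29, the luminal list by -0.78 at day 29, and the interferon list by 2.53 at day 21 and 1.64 at day 29. With the other reference, chosen after the data were seen, p53 targets did not pass (median 0.06 and 0.09) and luminal genes passed upward (median 0.01). The interferon list kept its direction (median 2.46 and 1.60), but did not pass with an estimated correlation in the planned comparisons (adjusted p = 0.101 and 0.375).

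The number of genes past the threshold was 32 at day 1, 2932 at day 3, 3198 at day 5, 9153 at day 21 and 8714 at day 29. The first became 133, 4, 6, 7, 3, 510, 57 and 11 without parental day 0 replicates 1 and 2, parental day 1 replicates 1 and 2, p53KO day 0 replicates 1 and 2, and p53KO day 1 replicates 1 and 2. At day 3 it became 1863 without parental day 0 replicate 2, 1610 without parental day 3 replicate 2, 1729 without p53KO day 0 replicate 1 and 1831 without p53KO day 3 replicate 1. At day 5 it became 1964 without p53KO day 5 replicate 1.

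The turn of the label difference between days 5 and 21 was weighed in its own right. If the labels of days 21 and 29 alone had been exchanged, p53 targets would be lower in libraries labelled p53KO at day 0, and their median was 0.30. Partial mixing of the lines in late cultures would shrink the differences without turning them, and genes at least 2-fold higher at day 0 had a median of -0.88 at day 29. That value is part of the turn itself, so it speaks only against mixing as the sole cause. Mixing beside another cause was not tested. An exchange of labels at days 0 to 5 needs p53 targets lower in libraries labelled p53KO at day 29. Their median there was -0.26. That reversal is part of the pattern to be explained, so it could not have excluded the exchange and adds no support for it. The exchange is a candidate explanation that stays open. A change of the lines themselves over weeks of treatment stays open too as a source of the turn, and was not tested. Acting only during treatment, it would not by itself cover the p53 targets at day 0. Of the 42 targets, 21 were higher and 5 lower in untreated libraries labelled p53KO.

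The interferon rise in libraries labelled p53KO at day 21 might come from a different line behind the label than at day 0. Against day 0 of the other label the list's median was still 2.79, which argues against that as the whole cause. Blood or endothelial cells would bring their abundant transcripts, and PTPRC, CD3E, CD68 and PECAM1 together reached at most 0.387 CPM in these libraries. The list of blood and endothelial markers, of which 5 of 23 were tested, did pass upward by fry at day 21. With day 0 of the other label as the reference its adjusted p was 0.00351. Against day 0 of its own label, markers past the threshold went both ways, and the adjusted p was 0.224 with no filter on low counts. The planned test of these markers is given below among the other observations. The interferon list was higher at day 29 too (median 1.63 against day 0 of the other label), which an effect on day 21 alone would not cover. Against day 0 of its own label the interferon list did not pass by fry at day 29 with only the groups compared (adjusted p = 0.0763). The length of treatment and a batch or culture effect stay open, and neither was tested.

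Mitotic genes in libraries labelled parental were higher at day 5 than at day 3, all 36 of the G2/M list (median 1.52, unadjusted p = 1.09e-07), a comparison chosen after the data were seen. Untreated cells mixed in at day 5 would bring cholesterol synthesis genes back toward day 0 as well, but their median way back was -1.38% against 11.5% for the G2/M genes. With total library size only the median was 1.62, which argues against TMM scaling as the cause. This outcome was near certain, since dropping TMM moved the median of all genes only from -0.004 to 0.096. The day of treatment itself stays open and was not tested as a cause.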

How the results depend on the processing

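The tests against day 0 or day 5 of the other label were chosen after the data were seen, and all other alternatives were fixed before. With DESeq2's size factors no count moved by more than 1.5 times and no named gene changed its call. Where a result changed, the cause was not tested, except that fitting only the groups compared and leaving out a library both lower the degrees of freedom. A group left with 1 library is assumed to vary like the others.

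The count most open to choices was the difference of response at day 1, 32 genes, which became 14 with total library size only, 316 with no filter on low counts, 50 with the replicate block, 15 with only the groups compared and 141 with DESeq2's Wald test. The difference at day 3, 2932 genes, became 1858 with only the groups compared. Replicate numbers did not pair the libraries, and the replicate block left the other counts within 1.5 times, for example 7416 for p53KO against parental at day 0.

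Leaving out 1 library in turn gave 5442 to 7272 genes for p53KO against parental at day 0 and 4559 to 5610 at day 29. For libraries labelled parental against day 0 it gave 1985 to 2632 at day 1, 5624 to 6630 at day 3, 5687 to 6017 at day 5, 10089 to 10700 at day 21 and 9865 to 10380 at day 29. For those labelled p53KO it gave 2966 to 5550, 6448 to 8203, 7972 to 9515, 11129 to 11763 and 9588 to 11042 at the same days. For the difference of response it gave 3 to 510, 1610 to 3660, 1964 to 3736, 8185 to 9147 and 7598 to 8908. For day 29 against day 5 it gave 7755 to 8736 in libraries labelled parental and 5139 to 5927 in those labelled p53KO.

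With total library size only, the share of higher genes moved from 49.8% to 39.9% in libraries labelled parental at day 3, from 45% to 60.3% in libraries labelled p53KO at day 1, from 32.8% to 57.8% for the difference at day 3 and from 34.9% to 47.6% for that at day 5. The median of all genes moved to 0.155 and 0.126 in libraries labelled parental at days 21 and 29, to 0.122, 0.141, 0.141 and 0.165 in those labelled p53KO at days 1, 5, 21 and 29, to 0.121 for the difference at day 3 and to 0.118 for parental day 29 against day 5. Lists turned their direction under this scaling for ribosome biogenesis and MYC in libraries labelled p53KO at day 1 (adjusted p = 0.665), lysosome genes in those at days 21 (0.806) and 29 (0.00118), unfolded protein genes in those at day 29 (0.00136), and lysosome genes for the difference at day 3 (0.0196) and parental day 29 against day 5 (0.046).

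Named genes kept their direction under every alternative fixed before, and 6 changed their call under at least 1. MDM2 at day 0 (0.0557) passed with total library size only (0.0353), no filter (0.0432), DESeq2's Wald test (0.0465), without parental day 0 replicate 2 (0.0213) and without p53KO day 0 replicate 1 (0.0195). CDKN2A at day 0 did not pass without p53KO day 0 replicate 1 (0.178), nor CCND1 without parental day 0 replicate 2 (0.0537). At day 1 the difference for CDT1, OAS3 and IRF7 did not pass with total library size only (0.0857, 0.0829 and 0.0829), nor CDT1 and IRF7 with only the groups compared (0.0652 for each), nor without the libraries named above.

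Fitting only the groups compared ended some list calls that the report gives, among them antigen presentation (0.0627) and unfolded protein genes (0.0605) at day 0. It also ended interferon genes in libraries labelled p53KO at day 29 against day 0 (0.0763), against day 5 (0.0594) and against parental (0.0946), and basal markers against parental at day 29 (0.0552). With camera in place of fry, 191 of the 261 lists that passed no longer did, and 0 passed by camera that had not by fry.

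With day 0 of the other label as the reference, the difference of response counted 6053 genes at day 21 and 3997 at day 29, and with day 5 of the other label, parental day 29 against day 5 counted 3778. Genes changed sign in libraries labelled parental at day 29 (SNCG 0.11, PHLDA3 -0.037) and in those labelled p53KO at day 29 (SEMA5A 0.95, BASP1 2.65, CRISPLD1 0.67, PHLDA3 0.12). Of these, only BASP1 and CRISPLD1 passed the threshold with the other reference. For the difference at day 29 they were SNCG (-0.63), CHRNA9 (-1.96), BASP1 (2.88), SEMA5A (0.87), RAMP3 (2.31), IGSF1 (2.03), HTRA1 (0.80), SERPINA1 (0.12), AGR2 (4.23), PHLDA3 (0.16) and EDA2R (0.44). Against day 5 of the other label they were CD44 in libraries labelled parental (-0.17) and MKI67 (-0.32), CCNE2 (-0.26) and EDA2R (0.024) in those labelled p53KO.

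Lists also turned with day 0 of the other label. These were p53 targets in libraries labelled parental at days 21 (adjusted p = 3.65e-05) and 29 (2.2e-06) and for the difference at days 21 (0.933) and 29 (0.0821), and luminal genes in those labelled parental at day 29 (0.0115), p53KO at days 21 (0.0519) and 29 (0.133) and for the difference at day 29 (0.004). Unfolded protein genes turned in libraries labelled p53KO at day 21 (1.24e-05) and for the difference at days 21 (0.0423) and 29 (0.166). For the difference alone, antigen presentation (1.72e-07 and 0.000195) and mesenchymal genes (0.00271 and 0.000361) turned at days 21 and 29, and nervous genes at day 29 (0.125). With day 5 of the other label, lists turned in libraries labelled parental for p53 targets (0.00225), G1/S (7.15e-06), homologous recombination (1.2e-05), interferon (0.00214), estrogen response (0.00452) and unfolded protein genes (0.232). In those labelled p53KO they turned for G1/S (0.000178), homologous recombination (0.000358), estrogen response (0.114), luminal (0.927), unfolded protein (0.0105) and ribosome biogenesis genes (0.0118).

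Small changes were recovered less often than large ones at these depths with 2 libraries per group. In simulated counts, 42.9% of genes changed 1.5-fold and 82.5% of those changed 4-fold were recovered for parental day 5 against day 0, and 21.9% and 73% for the difference of response at day 29.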

Other observations

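The list tests here were planned, and those against day 0 of the other label were chosen after the data were seen. Libraries labelled p53KO at day 21 also differed from day 0 in stress and growth programmes. Immediate early genes, which answer growth signals and stress, were higher, 15 of 27 against 4 lower (median 0.79, adjusted p = 1.1e-07, adjusted p = 0.159 with an estimated correlation; median 1.00 with the other reference). Hypoxia and glycolysis genes were lower, 15 of 25 against 7 higher (median -0.67, adjusted p = 9.55e-08, adjusted p = 0.302 with an estimated correlation; -0.41 with the other reference). Ribosome biogenesis and MYC genes were lower, 16 of 27 against 5 higher (6 and 16 adjusted over the list alone; median -0.34, adjusted p = 8.22e-08, adjusted p = 0.346 with an estimated correlation; -0.40 with the other reference).

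Markers of other cell states moved at day 29 in libraries labelled p53KO. Mesenchymal and fibroblast markers were higher, 8 of 15 against 3 lower (median 1.25, adjusted p = 4.83e-06, adjusted p = 0.255 with an estimated correlation; 0.76 with the other reference), and did not pass with only the groups compared (0.0509). Nervous and chromaffin cell genes were higher, 7 of 12 against 2 lower (median 1.49, adjusted p = 0.000479, adjusted p = 0.512 with an estimated correlation). Of the 5 blood and endothelial markers tested, 1 was higher and 1 lower at day 21, with a median of 0.42, a mean of -0.21 and an adjusted p of 0.0143, which became 0.224 with no filter on low counts. Lysosome and autophagy genes were higher in libraries labelled parental at day 5, 15 of 35 against 6 lower (median 0.07, adjusted p = 0.00698, adjusted p = 0.627 with an estimated correlation).

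The first 3 principal components held 35.7%, 21% and 10.9% of the variance. On the first, day 5 lay at -42 and -41.2 (labelled parental) and 54.4 and 51.3 (labelled p53KO). Day 29 lay there at 71.7 and 65.7, and at 23.1 and 31.5. On the second, the values in that order were -27 and -28.1, 24.7 and 25.8, 14.3 and 15.6, and -57.1 and -69.8. Parental day 29 thus lay nearer to p53KO day 5 than to parental day 5 on both. Libraries labelled p53KO at day 29 lay nearer to parental day 5 on the second only. Replicates with the same number in different groups were unrelated, with correlations from -0.0944 to 0.0978 over 66 pairs of groups.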
